A study of Mus musculus with 8 samples.

How the data were processed

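Expression was measured on 8 two-colour mouse arrays, each carrying cDNA from 1 siRNA pool against cDNA from a common reference pool. Per the labels, C57/BL6 embryos were electroporated in utero at embryonic day 14.5 with an siRNA (1 ug per ul) and a GFP vector (1 ug per ul), using 5 pulses of 33 V. Cortices were taken at embryonic day 16.5, dissociated and sorted, and RNA of the sorted cells was pooled. The groups were siFoxO6-2 (4 pools) and siFoxO6-3 (4 pools), which are different siRNAs against Foxo6. A single pool of cells that received a scrambled siRNA was the reference on all 8 arrays. The labels describe the 4 pools per siRNA as independent. Within each siRNA, replicates 2 and 4 carried the siRNA pool in Cy5 and replicates 1 and 3 carried it in Cy3.

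The deposited scanner files give spot intensity per channel, as mean and median over pixels, with a local background intensity, without correction. The extraction program is not stated. A deposited value table gives, per spot, a log2 ratio of the siRNA channel over the reference channel, centred near 0 on each array. How the authors made the log2 table is not stated, and its values follow the scanner log2 ratios with a correlation across spots of 0.86 to 0.98. The scanner intensities were used for all main values and the deposited table served as an alternative.

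Each array held 45220 spots, of which 41174 were gene probes and 4046 were controls. Mean spot intensities were background-corrected by normexp with an offset of 50 and normalized by loess within each array, with control spots at weight 0. This step assumes that at every intensity most genes do not change, so a shift shared by most bright genes would be removed. Of the gene probes, 34186 paired with 1 gene symbol, 0 with several and 6988 with none. Where a gene had several probes, the one with the highest mean intensity over the 8 arrays stood for it, which left 25310 tested genes or unnamed probes, 18322 of them with a symbol. A probe was counted as above the empty spots on an array when its signal exceeded the 97.5th percentile of 959 empty control spots in that channel. Gene symbols are those paired with the probes; 16254 of them had a record under the same symbol in the reference gene table, which was used for current names and gene lengths only.

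Log2 ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The model held 1 coefficient per siRNA, signed by dye orientation, and a constant dye term for each gene, with 5 residual degrees of freedom. The 4 comparisons were the mean of both siRNAs against scrambled, each siRNA against scrambled, and siFoxO6-3 minus siFoxO6-2. Tests were two-sided, and a gene was called when its Benjamini-Hochberg adjusted p in that comparison was under 0.05. P-values against scrambled carry the spread of the siRNA pools and leave out the spread of the reference, since only 1 reference pool existed. The reference could not be divided, so unchanged pools that share 1 reference pool as variable as an siRNA pool were simulated 20 times, as a bound on the likeness of the siRNAs.

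The 27 gene lists (825 genes, of which 743 matched by symbol, 16 through a synonym and 66 not at all) were fixed before the data were examined, as were the tests and most alternatives. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Per-array list means of the siRNAs were compared by an exact permutation test over the 35 splits of the 8 arrays. Named genes followed a rule set in advance. For both siRNAs together, these were the 12 largest rises and 12 largest falls among called genes with a symbol, the same sign on all 8 arrays and an intensity above the median. For each single siRNA they were the 5 largest in each direction by the same filters, and for the difference between siRNAs the 5 largest without the sign filter. Up to 4 members with the smallest p were taken per list, and Foxo6, Plxna4 and the other FoxO genes were always named. Pancreatic acinar, digestive-tract and sex-linked genes were examined as lists written after the first results.

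The procedure was tested on simulated data of 25310 genes per comparison. With both siRNAs together, 88.1% of changed genes were recovered at a log2 change of 0.5 and 100% at 1, with 9 false among 201 calls. For the difference between siRNAs, 52.2% were recovered at 0.5, 88.1% at 1 and 97.0% at 1.5, with 14 false among 172 calls. These simulated arrays had independent noise and no deviation of the reference pool. The false calls against scrambled therefore leave out errors of that pool. Unchanged pools simulated with 1 variable reference pool gave 3743 calls with siFoxO6-2 and 3767 with siFoxO6-3, as means over 20 runs. The alternatives covered background, normalization, dim probes, the dye term, a replicate block, the deposited table, the probe rule, the variance model, array weights, single-siRNA fits, the correlation in the list test, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays limits the precision of every value. Seed matches of the siRNAs in transcripts and slide or scan batches were planned and not tested, because no transcript sequences and no batch records were available.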

Results

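The data describe gene expression in sorted cells of the mouse embryonic cortex 2 days after in utero electroporation with siRNA against Foxo6, a FoxO transcription factor. There were 4 pools with siFoxO6-2 and 4 pools with siFoxO6-3, each hybridized against the same reference pool that had received scrambled siRNA. The median siRNA-channel signal ran from 58.0 (siFoxO6-3 replicate 4) to 123 (siFoxO6-2 replicate 4), over backgrounds of 44 to 54. Between 72.9% and 87.2% of probes were above the empty spots in the siRNA channel and 54.3% to 85.9% in the reference channel. Across genes, siFoxO6-2 replicate 3 (median r = 0.26 with the other arrays), siFoxO6-3 replicate 3 (0.28) and siFoxO6-3 replicate 4 (0.14) resembled the other arrays least.

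The first question was whether the siRNAs lowered their target. Foxo6 fell with both siRNAs together by 1.30 on the log2 scale (SE 0.07, n = 8 arrays, limma adjusted p = 0.0013), to 0.406 of the level in the scrambled pool, and was lower on 8 of 8 arrays. The mean log2 ratio of Foxo6 was -0.95 ± 0.41 (SD, n = 4) with siFoxO6-2 and -1.65 ± 0.49 (SD, n = 4) with siFoxO6-3. Foxo6 had adjusted p = 0.0055 and 0.0079 in these single-siRNA comparisons, and the difference between the siRNAs was -0.71 (adjusted p = 0.312). Plxna4, the guidance receptor named in the title of the series, fell by 1.05 (SE 0.09, limma adjusted p = 0.0017, 8 of 8 arrays lower). Its mean log2 ratio was -1.16 ± 0.37 (SD, n = 4) with siFoxO6-2 and -0.95 ± 0.15 (SD, n = 4) with siFoxO6-3. The other Plxna4 probe above the empty spots on all 8 arrays stood at -0.07 (adjusted p = 0.328), so the fall rests on 1 of its probes; the mean of its probes gave -0.38, still called. The related factors Foxo1 (-0.01), Foxo3 (-0.04) and Foxo4 (-0.01) were not called, although a second, nearly as bright Foxo1 probe stood at -0.24 (adjusted p = 0.0155). Median centring in place of loess gave -0.69 for Foxo6 (adjusted p = 0.0672) and -0.49 for Plxna4 (adjusted p = 0.108). Without siFoxO6-3 replicate 1 or siFoxO6-3 replicate 2, Foxo6 was no longer called with siFoxO6-3 (-1.64 with adjusted p = 0.138, and -1.53 with adjusted p = 0.0595).

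**Figure D1:**
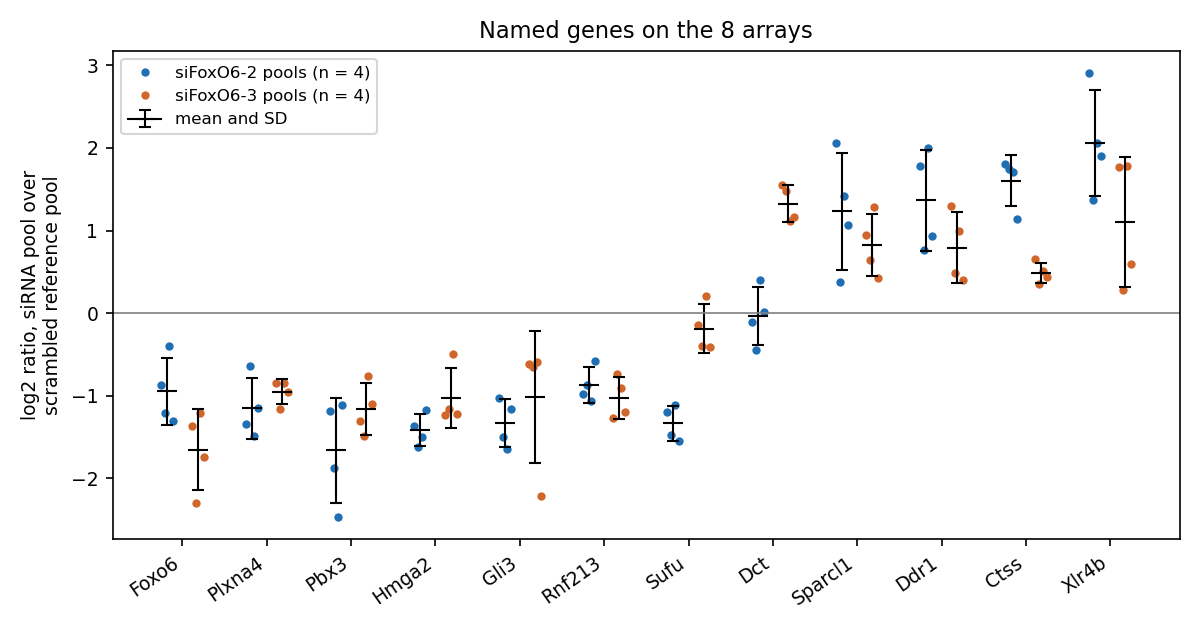
Log2 ratio of the siRNA pool over the scrambled reference pool (vertical axis) for 12 genes (horizontal axis), with a point per array, 4 for siFoxO6-2 and 4 for siFoxO6-3, and bars for mean and SD. Foxo6 and Plxna4 lay below 0 on 8 of 8 arrays, and Sufu and Dct differed most between the siRNAs among the genes drawn.

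The next comparison asked which genes differed from the scrambled pool with both siRNAs together. The genes that rose most were Xlr4b (log2 1.58, SE 0.11, n = 8 arrays), an X-linked lymphocyte-regulated gene, the repair and proteasome factor Rad23b (1.09), the collagen receptor kinase Ddr1 (1.08) and the lysosomal protease cathepsin S, Ctss (1.04). They were followed by Sparcl1 (1.03), the neuropeptide FF receptor Npffr2 (1.02), Xlr3c (0.94), lysozyme Lyz2 (0.87), the synaptic vesicle protein Synpr (0.87), Gtf2h5 (0.86), cathepsin L, Ctsl (0.86), and Unc84a (0.85), now named Sun1. The deepest falls were in the digestive enzymes Amy1 (-2.29, SE 0.43), Amy2a4 (-2.15) and Pnlip (-2.04). The transcription factor Pbx3 (-1.41, SE 0.16), the kinase subunit Pik3ca (-1.30), the chromatin protein Hmga2 (-1.23, SE 0.09), the exocyst subunit Exoc5 (-1.20), the immediate early factor Egr1 (-1.18), the Hedgehog pathway factor Gli3 (-1.18), Lrrc7 (-1.10) and Csmd1 (-1.08) also fell. The naming rule took only genes with the same sign on 8 of 8 arrays, so that agreement adds no support. With median centring none of these falls was called: Pnlip stood at -1.93, Amy2a4 at -1.88, Amy1 at -1.71, Pbx3 at -0.87, Hmga2 at -0.84, Lrrc7 at -0.78, Csmd1 at -0.76, Pik3ca at -0.63, Egr1 at -0.57, Gli3 at -0.54 and Exoc5 at -0.51. The rises stayed called, from 1.13 (Xlr3c) to 1.94 (Xlr4b). As the mean of all their probes, Xlr4b (0.82), Rad23b (0.27), Npffr2 (0.45), Lyz2 (0.49), Synpr (0.43), Gtf2h5 (0.43), Amy1 (-0.93), Pnlip (-0.95), Pik3ca (-0.47), Hmga2 (-0.47), Pbx3 (-0.38), Gli3 (-0.31), Lrrc7 (-0.27), Exoc5 (-0.27) and Csmd1 (-0.16) were smaller by over 1.5 times and still called. Second probes gave the same direction for Sparcl1 (0.90, adjusted p = 0.0154) and Pbx3 (-0.49, adjusted p = 0.0108). The second-brightest probes of Rad23b (-0.07), Pik3ca (0.37), Hmga2 (-0.07), Exoc5 (0.17), Csmd1 (-0.05), Amy1 (0.43), Pnlip (0.14) and Npffr2 (-0.12) did not follow and were not called. Without siFoxO6-2 replicate 4 the falls of Amy1 (-2.03), Amy2a4 (-1.96), Pnlip (-1.78) and Egr1 (-1.08) were no longer called, and the same held for Amy1 (-2.23), Pnlip (-1.98) and Egr1 (-1.12) without siFoxO6-2 replicate 2, Pnlip (-2.15) without siFoxO6-3 replicate 2 and Egr1 (-1.25) without siFoxO6-3 replicate 1.

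In all, 3367 of 25310 genes and unnamed probes were called with both siRNAs together, 1700 higher (50.5%) and 1667 lower. Of the 18322 genes with a symbol, 2767 were called. Other counts over all genes include unnamed probes in the same way. Of the 3367 called, 362 changed more than 1.5-fold and 23 more than 2-fold (8 higher, 15 lower). Where a called gene had 2 or more bright probes (696 genes), the second-brightest probe had the same sign in 508. A call therefore rests on 1 probe and need not hold for the other probes of the gene. Median centring called 473 genes, 97.0% of them higher, and kept the direction of 68.3% of the 3367. It also put the median of all genes at 0.11, so values after median centring are to be read beside that shift. The count was 1608, 2114, 5499 and 1526 without siFoxO6-2 replicates 1, 2, 3 and 4 in turn, and 1630, 1564 and 2223 without siFoxO6-3 replicates 1, 2 and 3. When the reference pool was given the spread of an siRNA pool, an alternative chosen after the data were seen, 0 genes were called by limma (635 at an unadjusted p under 0.05, against 7008 without that spread).

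Among the 26 lists tested, S phase genes had the lowest mean with both siRNAs together (log2 ratio -0.30 over 28 measured members). Of these, 0 were higher and 14 lower, or 15 lower when adjusted over the list alone. Median centring turned the list mean to 0.18, where the median of all genes stood at 0.11. The S phase genes that fell included Uhrf1 (-1.03, with a second probe at -0.94), which maintains DNA methylation, the replicative helicase subunits Mcm2 (-0.76) and Mcm3 (-0.84), and the origin licensing factor Cdc6 (-0.43). With median centring Uhrf1 (-0.41), Mcm2 (-0.22), Mcm3 (-0.15) and Cdc6 (-0.17) were not called; as the mean of its probes Mcm3 stood at -0.51, still called. Their list had adjusted p = 0.417 with an estimated correlation. Of 31 plexins, semaphorins and neuropilins, 0 rose and 6 fell (7 adjusted over the list alone), with a mean of -0.12 that median centring turned to 0.18. Besides Plxna4 these were led by the co-receptor Nrp1 (-0.57) and Sema4g (-0.24), at -0.10 and -0.09 and not called with median centring. A second, nearly as bright Nrp1 probe stood at -0.17 (adjusted p = 0.652; 0.21 with siFoxO6-2 and -0.56 with siFoxO6-3), and a dimmer one fell by 0.27 (adjusted p = 0.0242); the mean of the Nrp1 probes was -0.23, still called. The list had adjusted p = 0.259 with an estimated correlation, and was not called without siFoxO6-2 replicate 3 (mean -0.10) or siFoxO6-3 replicate 1 (-0.12). Of 30 immediate early and dissociation stress genes, 0 rose and 5 fell (6 adjusted over the list alone), among them Egr1, Cyr61 (-0.49), now named Ccn1, and the heat shock protein Hsph1 (-0.49). Their mean was -0.14, against 0.17 with median centring, which also turned Hsph1 to 0.20 and ended the calls of Egr1 and Cyr61 (-0.04), and adjusted p = 0.356 with an estimated correlation.

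Of 39 FoxO target genes known from other tissues, 8 rose and 1 fell (9 and 3 adjusted over the list alone; mean 0.09). Txnip (0.49; 0.26 as the mean of its probes, still called, with its second probe at 0.03), an inhibitor of thioredoxin, and the PI3K inhibitor Pik3ip1 (0.29) were among those that rose. The list had adjusted p = 0.259 with an estimated correlation. Of 23 p53 response genes, 5 rose and 1 fell (14 and 2 adjusted over the list alone; mean 0.18), with Ei24 (0.68) and Eda2r (0.53) higher and Zmat3 lower (-0.55, but 0.05 with median centring and -0.29, still called, as the mean of its probes). Eda2r stood at 1.07 with siFoxO6-2 and at -0.02 with siFoxO6-3, and at 0.20 as the mean of its probes, still called. Adjusted p = 0.259 was found for them with an estimated correlation. Of 25 microglia and macrophage markers, 7 rose and 1 fell, over all genes and adjusted over the list alone (mean 0.13). Ctss, Lyz2, Csf1r (0.46, not called with median centring at 0.86, and 0.16 as the mean of its probes, with the others at 0.06 and -0.04) and Aif1 (0.28) were among those that rose, with adjusted p = 0.417 for the list with an estimated correlation. Of the 26 lists, these 6 were called at the preset correlation, 0 with an estimated correlation and 6 by fry, which asks only whether a list moved one way. The estimated correlation was -0.004 for plexins and -0.008 for FoxO targets, below the preset 0.01. Correlation among their members is thus not what ended the calls of these lists in that form of the test. The plexin, FoxO target and immediate early lists were not called with the deposited table (adjusted p from 0.0577 to 0.108). Without dim probes these 3 and the microglia list were not called (adjusted p of 0.0586 or more). S phase and p53 response genes stayed called in both. Plexins were also not called with array weights, with 2 arrays left out together or with the gene-length settings (adjusted p from 0.0629 to 0.0825). With every probe tested by itself FoxO targets were not called (0.05, adjusted p = 0.205).

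**Figure D2:**
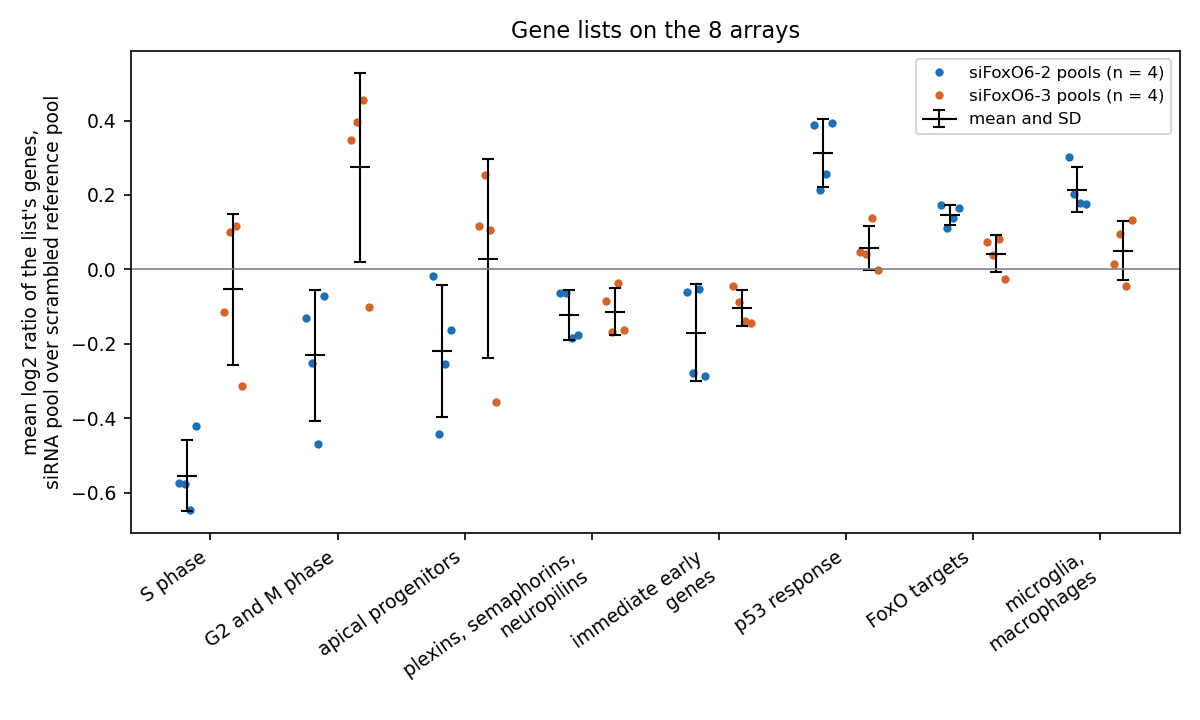
Mean log2 ratio over the genes of 8 lists (horizontal axis) on each array, siRNA pool over scrambled reference pool (vertical axis), with a point per array, 4 per siRNA, and bars for mean and SD. S phase genes averaged -0.55 with siFoxO6-2 and -0.05 with siFoxO6-3. The mean over both turned from -0.30 to 0.18 with median centring, where the median of all genes stood at 0.11. Means of plexins and of immediate early genes also changed sign then.

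For siFoxO6-2 alone, Xlr4b (log2 2.06 ± 0.64, SD, n = 4), Ctss (1.60 ± 0.31), D0H4S114 (1.51 ± 0.38), now named Nrep, Ddr1 (1.37 ± 0.61) and Rad23b (1.28 ± 0.22) rose most. Pbx3 (-1.66 ± 0.63), Exoc5 (-1.54), Pik3ca (-1.54), Egr1 (-1.54 ± 0.91) and Uhrf1 (-1.46 ± 0.18) fell most. With median centring none of these 10 was called, the falls running from -1.12 (Pbx3) to -0.82 (Exoc5), and as means of their probes Exoc5 (-0.35) and Pik3ca (-0.47) were not called, while Xlr4b (1.05), D0H4S114 (0.90), Rad23b (0.31) and Pbx3 (-0.46) were smaller by over 1.5 times and still called. Fitted on the siFoxO6-2 arrays alone, Pbx3, Exoc5 and Pik3ca were not called (adjusted p from 0.0553 to 0.0661). D0H4S114 was no longer called without siFoxO6-2 replicate 1 (1.48) or 4 (1.32), Exoc5 without siFoxO6-2 replicate 4 (-1.59), and Egr1 without siFoxO6-2 replicate 1 (-1.83), 2 (-1.41) or 4 (-1.33) or siFoxO6-3 replicate 1 (-1.54). In total, 2224 genes were called (1836 with a symbol), 1089 higher and 1135 lower. Of 28 S phase genes, 0 rose and 15 fell (20 adjusted over the list alone; mean -0.55, or -0.07 and not called with median centring), and adjusted p = 0.322 was found with an estimated correlation. Of 32 G2 and M phase genes, 0 rose and 6 fell (7 adjusted over the list alone), with a mean of -0.23 that median centring turned to 0.26 and adjusted p = 0.727 with an estimated correlation; without siFoxO6-2 replicate 3 the mean was -0.12 and the list not called. Of 30 apical progenitor markers, 1 rose and 9 fell (2 and 10 adjusted over the list alone), with a mean of -0.22 against 0.35 with median centring. The median of all genes with siFoxO6-2 was 0.093 after median centring. The apical list had adjusted p = 0.727 with an estimated correlation. Apical markers lower with siFoxO6-2 included Cdon (-1.27), Gli3 (-1.34), the intermediate filament Nes (-0.65) and Notch2 (-0.28). With both siRNAs together, median centring ended the calls of Cdon, Gli3 and Notch2 and turned Nes to 0.055. The apical list was not called without siFoxO6-2 replicate 2 (mean -0.16) or 3 (-0.17). P53 response genes (7 rose, 1 fell of 23; 10 and 2 adjusted over the list alone), FoxO targets (6 and 0 of 39; 8 and 1 adjusted over the list alone) and microglia and macrophage markers (6 and 1 of 25; 8 and 1 adjusted over the list alone) had means of 0.31, 0.15 and 0.21. With an estimated correlation their lists had adjusted p = 0.183, 0.183 and 0.330. With every probe tested by itself, G2 and M phase genes (-0.11) and FoxO targets (0.09) were not called. The number of called genes was 383 without siFoxO6-2 replicate 1, 975 without siFoxO6-2 replicate 2, 4281 without siFoxO6-2 replicate 3, 352 without siFoxO6-2 replicate 4, 1462 without siFoxO6-3 replicate 2 and 0 with median centring (limma, 5324 at an unadjusted p under 0.05).

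For siFoxO6-3 alone, Dct (log2 1.33 ± 0.22, SD, n = 4), a melanin synthesis enzyme, Xlr4b (1.11 ± 0.79), Scrg1 (1.10 ± 0.27), the linker histone Hist1h1c (1.01 ± 0.18), now named H1f2, and Rad23b (0.90 ± 0.32) rose most. Foxo6, Lrrc7 (-1.22 ± 0.29), Csmd1 (-1.06 ± 0.41), Rnf213 (-1.03 ± 0.25) and Hmga2 (-1.03 ± 0.36) fell most. Without siFoxO6-3 replicate 1 or 2 none of these genes was called, with log2 ratios from -1.64 (Foxo6) to 1.27 (Dct) and from -1.53 (Foxo6) to 1.23 (Dct). Without siFoxO6-2 replicate 1 Foxo6 alone among them stayed called, the others having adjusted p from 0.0574 to 0.0739. Xlr4b, Lrrc7 and Csmd1 were lost without any other single array except siFoxO6-2 replicate 3. Rad23b was lost without siFoxO6-2 replicate 4 or siFoxO6-3 replicate 3 or 4, Hist1h1c without siFoxO6-3 replicate 3 or 4, Scrg1 without siFoxO6-3 replicate 3, and Dct and Hmga2 without siFoxO6-3 replicate 4. With median centring none was called either, with Rnf213 at -0.53 and Hmga2 at -0.64, and as means of their probes Rad23b (0.23), Lrrc7 (-0.33) and Csmd1 (-0.16) were not called, while Xlr4b (0.59), Rnf213 (-0.53) and Hmga2 (-0.39) were smaller by over 1.5 times and still called. Fitted on the siFoxO6-3 arrays alone, Rad23b, Csmd1 and Hmga2 were not called (adjusted p from 0.0565 to 0.0706). Xlr4b was also lost without the dye term, Csmd1 without background correction and with every probe tested by itself, and both with a trended robust variance. A replicate block, although the numbers do not pair the pools, ended calls that included Dct, Hist1h1c, Rad23b, Lrrc7, Csmd1, Rnf213 and Hmga2. In total, 228 genes were called (195 with a symbol), 107 higher and 121 lower, and 0 with median centring (limma, 3617 at an unadjusted p under 0.05). Of 32 G2 and M phase genes, 1 rose, the cyclin-dependent kinase partner Cks2 (0.84), and 0 fell (5 and 0 adjusted over the list alone); the list mean was 0.27, with adjusted p = 0.541 with an estimated correlation. Of 18 oligodendrocyte and astrocyte lineage genes, 1 rose, Olig1 (0.62), and 0 fell (5 and 0 adjusted over the list alone; mean 0.17, 0.15 and not called without siFoxO6-3 replicate 4), with adjusted p = 0.520 with an estimated correlation. Plexins and their partners (mean -0.11, 1 fell; 1 higher and 4 lower adjusted over the list alone), immediate early genes (-0.10, 0 called, 0 adjusted over the list alone) and cholesterol synthesis genes (-0.13, 0 called, 3 lower adjusted over the list alone) were lower as lists. Their means turned to 0.17, 0.19 and 0.33 with median centring, where the median of all genes with siFoxO6-3 was 0.11. Their lists had adjusted p = 0.413, 0.539 and 0.541 with an estimated correlation. Without siFoxO6-3 replicate 1 these 3 lists were not called (-0.12, -0.10 and -0.11), nor were immediate early genes without siFoxO6-3 replicate 3 (-0.06) or cholesterol genes without siFoxO6-3 replicate 4 (-0.08). Oxidative phosphorylation genes had a mean of 0.11 (0 called; 4 higher and 1 lower adjusted over the list alone), with adjusted p = 0.905 with an estimated correlation and a mean of -0.01 without siFoxO6-3 replicate 4; it was not called without siFoxO6-2 replicate 1, 3 or 4 either (0.11 each). That list was also lost without background correction, without dim probes, with every probe tested by itself, with array weights and with the length trend removed (adjusted p from 0.0508 to 0.188). Immediate early genes were lost without background correction and with the deposited table, and cholesterol genes with every probe tested by itself (-0.06). The number of called genes was 2 without siFoxO6-2 replicate 1, 155 without siFoxO6-2 replicate 2, 1188 without siFoxO6-2 replicate 3, 62 without siFoxO6-2 replicate 4, 0 without siFoxO6-3 replicate 1 or 2 (limma, 2618 and 2582 at an unadjusted p under 0.05), 18 without siFoxO6-3 replicate 3 and 23 without siFoxO6-3 replicate 4.

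Both siRNAs called 184 genes in the same direction, 78 higher and 106 lower, and 0 in opposite directions. Foxo6, Plxna4, Xlr4b, Rad23b, Ddr1, Synpr, Hmga2, Lrrc7, Csmd1, Rnf213, Pcp4, Crym, Olig1, Zmat3 and Ddit4 were among them. The shared count was 2, 119, 768 and 34 without siFoxO6-2 replicates 1, 2, 3 and 4 in turn, 0 without siFoxO6-3 replicate 1 or 2, 16 and 19 without siFoxO6-3 replicates 3 and 4, and 0 with median centring. Lists drawn independently would share 4.60 higher and 5.43 lower genes. Across genes the log2 ratios of the siRNAs correlated with r = 0.68 (covariance 0.0253), where genes are not independent replicates. Simulated unchanged pools that shared 1 reference pool as variable as an siRNA pool gave r = 0.80 and a covariance of 0.0319. These values follow from the setting, which gave the reference the residual spread of the arrays, since its own spread could not be measured. The observed correlation and covariance were thus no larger than such a shared reference alone can give. That simulation gave 2094 shared calls among 3743 with siFoxO6-2 and 3767 with siFoxO6-3. The data held 2224 and 228 calls, so the counts of shared calls cannot be compared. Of the siFoxO6-3 calls in the data, 80.7% were shared. Between arrays, the mean correlation was 0.385 within an siRNA and 0.357 between siRNAs (exact one-sided permutation p = 0.343, smallest possible 0.0286).

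**Figure D3:**
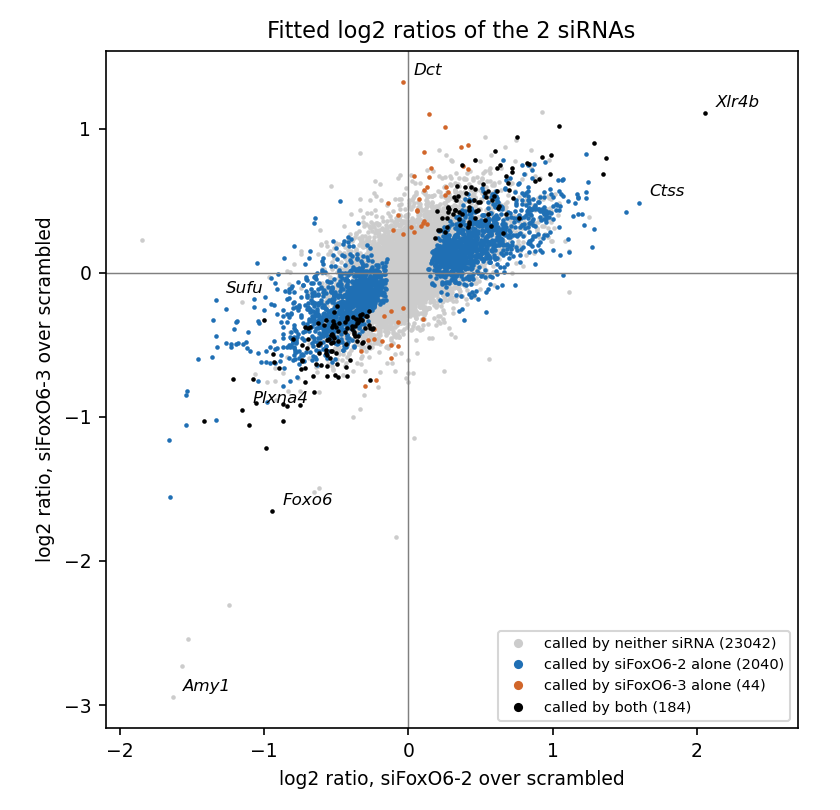
Fitted log2 ratio over scrambled with siFoxO6-2 (horizontal axis) and siFoxO6-3 (vertical axis), with a point per tested gene, coloured by which siRNA called it. Of the genes drawn, 184 were called by both siRNAs, 2040 by siFoxO6-2 alone and 44 by siFoxO6-3 alone, and all 184 lie in the quadrants where the signs match.

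The last comparison asked where the siRNAs differed from each other, the only one with replicate pools on both sides. Sufu, a negative regulator of Hedgehog signalling, was the 1 gene called: its log2 ratio was -1.34 ± 0.21 (SD, n = 4) with siFoxO6-2 and -0.19 ± 0.29 (SD, n = 4) with siFoxO6-3. The difference for Sufu was 1.15 (SE 0.08, limma adjusted p = 0.0445), and its other probe above the empty spots on all arrays stood at 0.04 and 0.02. With median centring (1.24) and as the mean of its probes (0.36) the difference for Sufu was not called. Nor was it called without the dye term, with the deposited table, with every probe tested by itself, with a trended robust variance, with pixel medians or without siFoxO6-2 replicate 3 and siFoxO6-3 replicate 4 together (1.15 to 1.27, adjusted p from 0.0513 to 0.167). Dct (-0.04 against 1.33, adjusted p of the difference 0.160) and Ctss (1.60 against 0.49, adjusted p = 0.122) differed without passing. S phase genes averaged -0.55 ± 0.10 (SD, n = 4) with siFoxO6-2 and -0.05 ± 0.20 with siFoxO6-3 (exact permutation p = 0.0286, the smallest possible, adjusted 0.154). G2 and M phase genes averaged -0.23 ± 0.18 and 0.27 ± 0.25 (exact permutation p = 0.0571, adjusted 0.220). In each of these lists 15 genes were higher with siFoxO6-3 and 0 lower when adjusted over the list alone, and 0 over all genes. The lists had adjusted p = 0.160 and 0.207 with an estimated correlation. Among their members, Mcm2 (-1.26 against -0.25), Mcm3 (-1.35 against -0.33), Cdca3 (-0.68 against 0.15), Plk1 (-0.53 against 0.05) and Tpx2 (-0.60 against 0.08) each had an adjusted p of the difference from 0.216 to 0.300. Apical progenitor markers also stood lower with siFoxO6-2 (-0.22 against 0.03, exact permutation p = 0.171, adjusted 0.514). P53 response genes (0.31 against 0.06), microglia and macrophage markers (0.21 against 0.05) and FoxO targets (0.15 against 0.04) stood higher with siFoxO6-2, and the oligodendrocyte and astrocyte lineage lower (0.01 against 0.17; exact permutation p = 0.0286, adjusted 0.154, for each). Xist was lower than in the reference on siFoxO6-2 replicates 1, 3 and 4 and on siFoxO6-3 replicate 1, and higher on the other 4 arrays.

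For the difference, 1838 genes had an unadjusted p under 0.05, and 11 lists were called at the preset correlation, 0 with an estimated correlation and 0 by fry. Without siFoxO6-2 replicate 4 the 1 called gene was not Sufu, and Sufu was the called gene without siFoxO6-3 replicate 3. Leaving out siFoxO6-2 replicate 3 gave 4 called genes, and leaving out siFoxO6-2 replicate 1 or 2, or siFoxO6-3 replicate 1, 2 or 4, gave 0 (limma, 1405 to 1972 at an unadjusted p under 0.05). In these fits, apart from the one without siFoxO6-2 replicate 3, a lost call for Sufu came with a difference of 1.12 to 1.21 (adjusted p from 0.0703 to 0.441).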

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

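The test of progenitor share was chosen after its result was seen, as was the weight given to the proteases in the test of acinar RNA; the other tests in this part were written before the values they measure were looked at. Of 172 groups of 4 arrays examined, 12 held an array far from the other arrays of its siRNA, where chance gives about 1 in 20.

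Pancreatic enzyme genes were far lower on 1 array: with siFoxO6-3 replicate 1, Amy1 stood at -5.34, Amy2a4 at -4.98 and Pnlip at -5.00, and the proteases Cela3b at -3.53, Prss2 at -3.41 and Prss3 at -2.47, while the other siFoxO6-3 arrays lay between -2.25 and -1.53 for the first 3 genes, between -0.98 and -0.73 for Prss2 and between -0.48 and -0.41 for Prss3. Over the 8 arrays Cela3b (mean -1.09), Prss2 (-1.06) and Prss3 (-0.64) followed Amy1 (r = 0.97, 0.97 and 0.95) and were lower on 8 of 8 without being called (adjusted p = 0.0623, 0.0621 and 0.117). All 8 arrays hold the same reference pool, so RNA in it cannot by itself set 1 array apart (Amy1 was -0.36 on siFoxO6-2 replicate 1). The siRNA pools or the arrays would also have to differ, which was not tested. For the fall over the 8 arrays, pancreatic acinar RNA in the reference pool cannot be told apart from a change in the genes. The other 18 acinar genes above the empty spots had a median log2 ratio of -0.055, above the bound of -0.1 set against it beforehand. Cpa1 (-0.19), Clps (-0.04) and Ctrb1 (-0.07) lay near 0 on siFoxO6-3 replicate 1. However, the median covers these moving proteases as well as unmoved genes, and 15 of the 18 (83.3%) were below 0. Cross-hybridization within the amylase and lipase families would leave these proteases in place, and also cannot be told apart for Amy1, Amy2a4 and Pnlip, because the 17 acinar genes of other families had a median of -0.050. Of 17 genes of other digestive epithelium and liver, Alb (-0.50, adjusted p = 0.00699, 8 of 8 arrays lower) and Ttr (-0.44, adjusted p = 0.0455, 7 of 8) fell and Trf rose (0.17, adjusted p = 0.0436), while the second probes of Amy1 (0.43) and Pnlip (0.14) did not fall, and no biological explanation was tested.

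List means stood lower with siFoxO6-2 than with siFoxO6-3 for S phase genes (by 0.50), G2 and M phase genes (0.51) and apical progenitor markers (0.25). These lists were called by camera at its preset correlation only. With an estimated correlation camera gave adjusted p = 0.160, 0.207 and 0.447, and no exact permutation test of them passed after adjustment. A lower share of progenitors among the siFoxO6-2 cells may underlie this, and cannot be told apart from a change of cell cycle genes within cells: the apical difference of 0.25 exceeded the spread of arrays (0.23), while intermediate progenitor markers differed by 0.02 (spread 0.11, median 0.077). As to chance, 3 of 34 splits of the arrays called at least 1 gene, the real split and 2 others with 1 each, so chance is not excluded for the gene called between the siRNAs. The 1 gene called in these other splits was Xist in the one and Ccl4 in the other. The split that called Xist parted exactly the arrays with Xist below the reference from those with it above. It thus followed a real difference between the pools, and only the split that called Ccl4 remains as a chance relabelling. The siRNA is a biological difference of the design and stays open, as does the uneven level of sex-linked genes among the pools. Xist was below the reference on siFoxO6-2 replicates 1, 3 and 4 but only on replicate 1 of siFoxO6-3. The comparison of the siRNAs is therefore partly mixed with that level.

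The call of 3367 genes against scrambled with both siRNAs together was weighed against 3 explanations. As to chance, of 34 assignments of the dye orientation that could be fitted, 1, the real one, called as many genes. The highest other called 644. It differed from the real one only in exchanging siFoxO6-2 replicate 3 and siFoxO6-3 replicate 4. Both were among the arrays that resembled the others least (median r = 0.26 and 0.14). The log2 ratios thus followed the real orientation more than the other assignments. All arrays share the reference pool, so a chance deviation of that pool would follow the orientation as well. This test therefore cannot separate such a deviation from an effect of the siRNAs. Gene length as the whole cause is argued against by 97.4% of the called genes with a length (2689 of 2761) staying called once the length trend was removed from each array, the rank correlation with length being -0.04 over the fitted ratios, though -0.20 on siFoxO6-2 replicate 3 and -0.25 on siFoxO6-3 replicate 4. A deviation of the single reference pool cannot be told apart from an effect of the siRNAs: the covariance of the siRNAs was 0.791 of that in simulated unchanged pools, and every array holds the same reference. What stays open is that deviation, RNA quality, which was not tested, and the knockdown named by the design.

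Some arrays stood apart from the other 3 of their siRNA for a single gene. Ctss was 1.14 on siFoxO6-2 replicate 4, below 1.71 to 1.80 on the other arrays. Lyz2 was 0.038 on siFoxO6-3 replicate 2, against 0.63 to 0.74. Gtf2h5 was 0.17 on siFoxO6-3 replicate 3, against 0.79 to 0.83. Hmga2 was -0.49 on siFoxO6-3 replicate 3, against -1.23 to -1.16. Gli3 was -2.22 on siFoxO6-3 replicate 4, against -0.66 to -0.59. Scrg1 was -0.053 on siFoxO6-2 replicate 2, against 0.18 to 0.22, and 1.50 on siFoxO6-3 replicate 4, against 0.97 to 0.98. Zmat3 was -0.36 on siFoxO6-2 replicate 1, against -0.46 to -0.45. Cyr61 was -0.24 on siFoxO6-3 replicate 1, against -0.67 to -0.60.

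The siRNAs also differed, as siFoxO6-3 minus siFoxO6-2, in Sufu (1.15, by the limma test of the difference) and, by camera at its preset correlation only, in 11 lists. Besides the 3 above, these list means differed by -0.10 for FoxO targets, -0.16 for microglia and macrophages, -0.076 for endothelial cells and pericytes, 0.15 for the oligodendrocyte and astrocyte lineage, -0.092 for the interferon response, -0.26 for the p53 response, 0.13 for oxidative phosphorylation and 0.13 for glycolysis and hypoxia. With an estimated correlation 0 of the 11 remained.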

How the results depend on the processing

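The pixel median, the joint removal of the least similar arrays, the gene-length settings and the spread given to the reference were chosen after seeing the data. Counts were taken as unchanged within 1.5 times of the main value, and the correlation of the siRNAs within its leave-one-out error. Calls of genes and lists were unchanged when they kept direction and side of the threshold. Over all alternatives, 206 of 293 values of the main results were unchanged, 77 moved and 10 calls were lost. For genes called higher or lower, 103 of 194 counts were unchanged and 91 moved. Unchanged were 603 of 696 list calls and 1680 of 1986 named-gene calls. In all, 295 named-gene calls and 82 list calls were lost, and 11 of each changed sign. Quantile scaling of intensities between arrays leaves the ratios untouched and so tests nothing, though its values are among those counted as unchanged. The cause of the changes below was not tested unless named.

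Median centring moved the median of all genes to 0.11 with both siRNAs. It called 473 genes with both siRNAs, 0 with siFoxO6-2, 0 with siFoxO6-3, 0 between them and 0 shared (limma, 5324, 3617 and 150 at an unadjusted p under 0.05 with siFoxO6-2, with siFoxO6-3 and between them; r = 0.89 between siRNAs, 14 lists), and left Foxo6 at -0.69, -0.31 and -1.06 (both, siFoxO6-2, siFoxO6-3) and Plxna4 at -0.49, none called. With both siRNAs it turned list means to 0.18 (plexins), 0.18 (S phase) and 0.17 (immediate early), with siFoxO6-2 to 0.35 (apical) and 0.26 (G2 and M), and with siFoxO6-3 to 0.17 (plexins), 0.19 (immediate early) and 0.33 (cholesterol). Among genes it turned Plxna3 to 0.31, Nes to 0.055, Cdca3 to 0.44, Plk1 to 0.29, Tpx2 to 0.22, Mbp to 0.054, Zmat3 to 0.046, Psat1 to 0.015, Slc3a2 to 0.21, Hsph1 to 0.20 and Jun to 0.11.

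Giving the reference the spread of 1 siRNA pool called 0 genes with both siRNAs, 0 with siFoxO6-2, 0 with siFoxO6-3 and 0 shared (limma, 635, 1124 and 396 at an unadjusted p under 0.05), with Foxo6 (-1.30, -0.95, -1.65) and Plxna4 (-1.05) unmoved in size and no longer called (adjusted p from 0.793 to 1.00) by construction. Array weights called 6152 genes with both siRNAs, 5970 with siFoxO6-2, 681 with siFoxO6-3, 20 between them and 544 shared. Leaving out siFoxO6-2 replicate 3 and siFoxO6-3 replicate 4 called 6376, 4943, 1628, 0 and 1192, with 18 lists between the siRNAs and oxidative phosphorylation at 0.015 with siFoxO6-3. Fits on each siRNA's own 4 arrays called 284 and 144 genes, 19 shared. The replicate block called 10 with siFoxO6-3, 9 shared and 0 between siRNAs, though the numbers do not pair the pools: deviations from the siRNA's mean correlated with r = 0.53, 0.22, -0.10 and -0.27 for numbers 1 to 4, and 0.27 and -0.13 within dye orientation. The mean of all probes called 134 with siFoxO6-3, 105 shared and 0 between siRNAs, and the pixel median 432, 329 and 0. Between siRNAs, 0 genes were called without the dye term, with the deposited table, with every probe tested by itself and with a trended robust variance, and 2 without background correction; these and the other settings with 0 between siRNAs, median centring apart, had 1405 to 3167 genes at an unadjusted p under 0.05. Lists called with both siRNAs were 2 without dim probes, 3 with the deposited table and 0 with an estimated correlation, which also left 0 between siRNAs.

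Leaving out 1 array at a time gave 1526 to 5499 called genes with both siRNAs, 352 to 4281 with siFoxO6-2, 0 to 1188 with siFoxO6-3, 0 to 4 between siRNAs and 0 to 768 shared. Correlation of the siRNAs ran from 0.55 to 0.68, lists from 5 to 8 with both siRNAs and 8 to 13 between them, Foxo6 from -1.35 to -1.24, -1.03 to -0.84 and -1.75 to -1.53 (both, siFoxO6-2, siFoxO6-3), and Plxna4 from -1.14 to -0.996. Oxidative phosphorylation changed sign to -0.0056 with siFoxO6-3 without siFoxO6-3 replicate 4; its difference between siRNAs, 0.13 on all arrays, ran from 0.015 without siFoxO6-3 replicate 4, where the test direction turned, to 0.251 without siFoxO6-2 replicate 3. Seed-match tests, including an 8-base seed, and a slide or scan block were not run. Signal over background limits dim genes: the weakest channel had a median of 58.0 over a background of 44.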

Other observations

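Deep-layer neuron genes split with both siRNAs together: of 27 measured, 5 rose and 4 fell (6 and 4 adjusted over the list alone). Among those that rose were Crym (log2 0.72, SE 0.06, n = 8 arrays), Pcp4 (0.67, SE 0.05; 0.33 as the mean of its probes, still called), the cell cycle inhibitor Rprm (0.52, with a second probe at 0.47) and the adhesion molecule Opcml (0.28, not called with median centring at 0.69 or as the mean of its probes at 0.06). The list was not called (camera adjusted p = 0.553). Upper-layer genes (3 rose, 5 fell of 22), intermediate progenitor markers (1 and 4 of 21), interneuron genes (1 and 2 of 23) and Cajal-Retzius markers (2 and 2 of 14) were not called as lists either.

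Of 33 genes of the unfolded protein and integrated stress response, 4 rose and 5 fell with both siRNAs (4 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.977). Ddit4, an inhibitor of mTOR signalling, rose by 0.54 (SE 0.05), while Asns (-0.50), Psat1 (-0.74) and Slc3a2 (-0.35; -0.16 as the mean of its probes) fell; with median centring none of these 3 was called, Asns standing at -0.02 and Psat1 and Slc3a2 turning to 0.02 and 0.21. Of 18 genes of the oligodendrocyte and astrocyte lineage, 5 rose and 1 fell, with Olig1 (0.57) and Gjb6 (0.25, not called with median centring at 0.48 or as the mean of its probes at 0.18) higher and Mbp lower (-0.39, but 0.05 with median centring and -0.13 as the mean of its probes). This list was not called (camera adjusted p = 0.208, and adjusted p = 0.684 with an estimated correlation).

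Sex-linked genes differed widely between arrays. Xist stood at -3.31, 1.58, -2.43 and -3.23 on siFoxO6-2 replicates 1 to 4 and at -3.15, 0.94, 1.80 and 1.32 on siFoxO6-3 replicates 1 to 4. Y-linked Eif2s3y stood at 1.35, -3.23, 0.33 and 1.20, and at 1.33, -3.65, -3.08 and -1.92, in the same order, with the opposite sign to Xist on all 8 arrays. The labels describe pooled cortices and give no sex. The Y-linked Kdm5d probe stood at -0.14 (adjusted p = 0.183) and Uty at -0.45 (adjusted p = 0.00686) over both siRNAs.

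One hypothesis was that more microglia or macrophages among the siFoxO6-2 cells may underlie the rise of their markers. Of the 10 markers brighter than the median gene, 8 (80%) were higher with siFoxO6-2, above the 75% set beforehand as its mark. Only 3 of the 10 were called, Ctss (1.60), Lyz2 (1.23) and Csf1r (0.75), while C1qb (-0.08) and Fcer1g (0.11), abundant in such cells, were not called. The requirement that most of these markers be called was added after their values were seen, so a larger share of these cells cannot be told apart from a rise of single genes. The cells had been sorted, but how far the sort removed microglia was not tested.

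Gene length went with direction among the calls with both siRNAs: among the 3658 shortest genes 220 were higher and 128 lower, and among the 3654 longest genes 211 were higher and 420 lower. The rank correlation with length was not of 1 sign over the arrays. It was -0.20 on siFoxO6-2 replicate 3, and -0.08 and -0.25 on siFoxO6-3 replicates 2 and 4. On siFoxO6-2 replicate 1 it was 0.09, on siFoxO6-3 replicates 1 and 3 0.11 and 0.09, and on siFoxO6-2 replicates 2 and 4 near 0.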
